A study of Homo sapiens with 12 samples.

How the data were processed

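Bulk RNA sequencing was read from 12 libraries of cerebral organoids grown from H1, an established human embryonic stem cell line. Organoids were wildtype or lacked FEZ1, and were collected at day 10 or day 60 of culture. The labels gave 4 groups: wildtype and knockout at day 10 with 4 libraries each, and wildtype and knockout at day 60 with 2 libraries each. RNA was extracted with TRIzol and the libraries were made by a sequencing company, per the labels' protocols. The labels do not state that the libraries of a group came from separate cultures, so the p-values of genes measure the spread between these libraries, which may be technical. Each label also starts with a code (B16, B27 or B29) whose meaning is not given. At day 10, replicates 1 and 2 of each genotype carry B16, replicate 3 B27 and replicate 4 B29, and all day 60 libraries carry B16.

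The authors deposited a table of raw counts per gene symbol and library, a table of normalized counts and a table of their own test. Per the submitters' processing notes, hg19, STAR, HTSeq and DESeq2 were used. Their versions and settings, the gene annotation and whether counting used the strand are not given in the sources used here. Without strand information, reads from positions shared by genes on opposite strands could not be told apart, and pseudogenes may share reads with their parent genes. The deposited counts are whole numbers with a different total in each library, from 15.7 M to 22.7 M. The signal in the authors' normalized table equals the deposited count divided by 1 factor per library, within a relative tolerance of 1e-06 for 100% of values, and covers 19365 genes, those with a total of at least 25 counts. It was used only for this check. The log2 fold changes and standard errors deposited by the authors compare FEZ1-null with wildtype organoids and were used only where the authors' deposited table is named. The p-values deposited by the authors go with these log2 fold changes, and 526 genes have an adjusted p below 0.05 in it. A DESeq2 fit of the deposited counts without independent filtering and with 3 groups, in which all day 60 libraries formed 1 group and the comparison was of genotypes at day 10, matched 99.99% of the authors' standard errors within 0.001 and also called 526 genes. A DESeq2 fit with 4 groups matched 2.57% of them and called 481 genes.

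Of 28207 genes in the count table, 3350 had no count in any library and 17757 passed edgeR's filterByExpr over the 4 groups. All 12 libraries entered 1 edgeR quasi-likelihood fit with 4 groups, TMM factors and robust estimation of the prior, so that the groups of 2 shared their estimate of the spread with the groups of 4. The knockout was compared with wildtype at each day, the difference of these effects between days was tested as an interaction, and day 60 was compared with day 10 in each genotype. Every adjusted p of a gene is from this quasi-likelihood F test with Benjamini-Hochberg adjustment over 17757 genes unless another tool is named, tests are two-sided, and genes with an adjusted p below 0.05 are called. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are CPM (edgeR's scaling of counts to library size times TMM factor), given as mean ± SD. Values on the log2 CPM scale use a prior count of 2. Differences within 1 label code, or between codes within 1 genotype, are differences of mean log2 CPM, with the median over members for a list. They are not fitted log2 fold changes. The prior pulls genes with few counts toward 0, and a gene without counts in the libraries compared gives 0. Lists were tested with limma's camera on the same fit with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera compares the members with the other genes. With this small preset, its p-values take little account of members that vary together between libraries, and do not measure replication across libraries. An estimated correlation and fry, a test of whether the members of a list move on balance in 1 direction, were run beside the preset. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

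The comparisons, the tests, 33 gene lists and the rule for naming genes were fixed before the data were examined. Of the 33 lists, 32 could be tested, because the remaining list had only 2 measured members. For each comparison of genotypes the rule names FEZ1, its paralogue FEZ2, and up to 8 genes with the largest rise and 8 with the largest fall among called genes. These need a mean of at least 5 CPM in the higher group, no overlap between the libraries of the groups, and a symbol that is not a clone name or a bare identifier. For the interaction and for day 60 against day 10 in wildtype the rule takes 5 and 5. From each list it takes up to 3 called members of a list, or up to 2 uncalled members with the smallest p, given as values. Genes outside the rule are said to be chosen after their values were seen. Some single-gene results are withheld for evaluation and not reported.

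Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with a 95% exact binomial interval. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules. Positions are from GENCODE release 29 on GRCh38, which matched 25540 of the 28207 symbols (90.5%), and were not converted to the build named by the submitters.

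The tests were checked on simulated counts drawn from the real means and library sizes, with 100 genes changed by 2-fold and 100 by 4-fold. For knockout against wildtype at day 10, 52% of the 2-fold and 86% of the 4-fold changes were called, with 8 false calls among 17546 genes. At day 60, 9% of the 2-fold and 76% of the 4-fold changes were called, with 4 false calls among 17553 genes. Counts were drawn for each gene independently, with the same mean in both genotypes of a day apart from the changed genes. Genes therefore did not shift together between libraries of a group, as they do in the real day 10 libraries. The numbers of false calls do not cover such shifts.

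The alternatives fixed beforehand were DESeq2 size factors in place of TMM, no low-count filter or a stricter one, no robust estimation, the label code as a covariate, the B16 libraries alone, the DESeq2 Wald test, only the libraries of the groups compared, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were a DESeq2 fit with all day 60 libraries as 1 group, a fit of the B27 and B29 libraries of day 10 with all day 60 libraries, a fit without the B16 wildtype libraries of day 10, and for the lists the covariate, the B16 libraries alone and the other size factors. No library was left out of the reported fit, and replicates of a group differed by more than sampling noise, with a chi-square per gene of 2.76 to 133.7.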

Results

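RNA-seq counts were compared between wildtype cerebral organoids and organoids lacking FEZ1, an adaptor protein of kinesin motors in axonal transport. The organoids were grown from H1 human embryonic stem cells, and 4 libraries per genotype were collected at day 10 and 2 per genotype at day 60. The series asks how FEZ1 affects the specification of neural progenitors and the migration of neurons in the developing brain. Total counts per library ranged from 15.7 M to 22.7 M. The component with the largest share of variance (75.8%) separated day 10 from day 60. Within day 10, the component with 57.5% of the variance set wildtype replicates 1 and 2, at -78.3 and -99.1, apart from the other 6 libraries, which lay between 16.2 and 38.7. These 2 libraries share the label code B16 with knockout replicates 1 and 2, which lay at 29.5 and 30.7. Knockout replicate 1 stood apart on the next component (-80.1), with 13.2% of its counts in ribosomal protein genes against 7.95% to 9.91% in the other knockout libraries of that day.

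FEZ1 transcripts were lower in every knockout library than in any wildtype library of the same day. At day 10 FEZ1 stood at 44.6 ± 3.59 CPM in wildtype (SD, n = 4) and 20.6 ± 1.49 CPM in knockout (n = 4), a log2 fold change of -1.11 ± 0.11 (SE; adjusted p = 0.00153). At day 60 it stood at 219 ± 30.1 CPM in wildtype (n = 2) and 48 ± 0.548 CPM in knockout (n = 2), a log2 fold change of -2.19 ± 0.16 (adjusted p = 0.000335). FEZ1 lies on the minus strand of chromosome 11 from 125442881 to 125592568 (GRCh38). The counts are per gene, so they do not show whether the remaining transcripts carry the edited sequence. FEZ2, the paralogue of FEZ1, had log2 fold changes of 0.14 ± 0.12 at day 10 (adjusted p = 0.679) and -0.01 ± 0.17 at day 60 (adjusted p = 1), and neither passed the test. In the authors' deposited table FEZ1 has a log2 fold change of -1.09 with an adjusted p of 0.189 and a standard error of 0.435, whereas a DESeq2 fit with the 4 groups kept apart gave a standard error of 0.121 and an adjusted p of 6.51e-16.

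**Figure D1:**
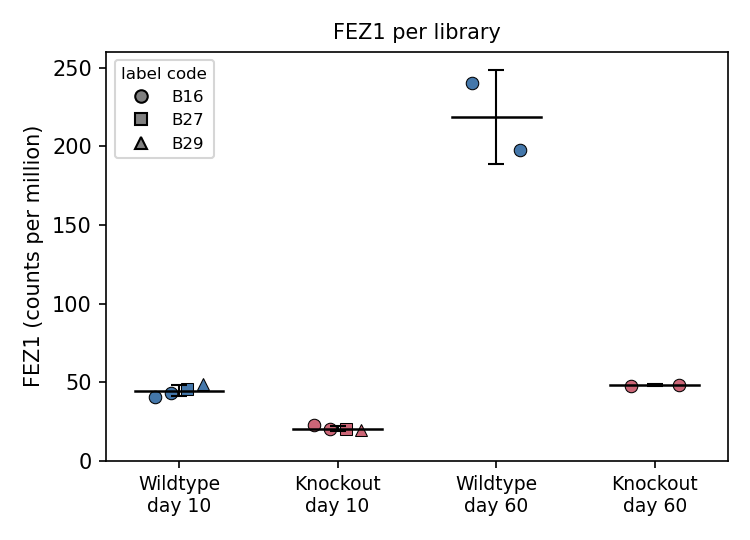
FEZ1 in CPM (y axis) for each library, by genotype and day (x axis), with symbols for the label code, lines for group means and bars for 1 SD. Knockout libraries of day 10 reach at most 22.7 CPM and wildtype libraries are at least 40.5 CPM, while the day 60 knockout libraries lie at 47.6 and 48.4 CPM against 197.4 and 239.9 CPM in wildtype.

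At day 10 transcripts were compared between genotypes in young organoids. CTSF, which encodes a lysosomal cysteine protease, fell from 25.1 ± 3.23 to 0.725 ± 0.179 CPM (34.3-fold lower; adjusted p = 0.000179), and the zinc finger gene ZNF280D fell from 19.8 ± 2.65 to 1.47 ± 0.637 CPM (adjusted p = 0.000182). SLITRK1, a synaptic adhesion protein, fell with a log2 fold change of -2.50 ± 0.35 (adjusted p = 0.0156), CACNA1E, a subunit of a voltage-gated calcium channel, with -2.37 ± 0.33 (0.0156), and SEZ6L with -1.67 ± 0.27 (0.0492). DCT, an enzyme of melanin synthesis in pigment cells, rose from 0.605 ± 0.246 to 5.49 ± 2.62 CPM (adjusted p = 0.0156). The gastrin and cholecystokinin receptor gene CCKBR rose by 1.91 ± 0.28 on the log2 scale, the piRNA-binding Argonaute gene PIWIL2 by 1.41 ± 0.18, the postsynaptic scaffold gene HOMER2 by 1.02 ± 0.15 and CCDC152 by 2.20 ± 0.24. All values are from 4 libraries per genotype, with SD beside CPM and SE beside log2 values.

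In all, 22 of 17757 genes were called at day 10, 7 higher and 15 lower, and 2178 had an unadjusted p below 0.05. The zinc finger gene ZNF562 fell with a log2 fold change of -0.76 ± 0.10. The pseudogenes UBBP4 (2.65 ± 0.20) and GUSBP4 (-3.82 ± 0.31) were also called, and reads of their parent genes may be counted in them. The remaining 8 called genes fell outside the rule for named genes and are named after their values were seen. Among them the imprinted gene PEG3 had 2 counts over the knockout libraries against 261 over the wildtype libraries, a ratio of 117.1 (95% interval 32.1 to 971.8). TSPYL5 had 1 count against 83, a ratio of 74.5 (13.0 to 2976). The noncoding RNA LINC02506 had a log2 fold change of -3.71 ± 0.33, ART3 of -4.84 ± 0.68, the chemokine gene CXCL11 of -3.95 ± 0.47 and LOC100288203 of -1.66 ± 0.26. The spans of ART3 and CXCL11 overlap on opposite strands of chromosome 4. Whether their exons overlap was not checked, so without strand information their counts may not be separate. LINC00680-GUSBP4, which overlaps GUSBP4 on the same strand, was at least 22.7-fold lower, and the pseudogene CYP4F24P had a log2 fold change of 4.33 ± 0.51.

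Of the 22 calls, 6 held in every alternative fit, namely those of CTSF, GUSBP4, LINC02506, PEG3, UBBP4 and ZNF280D, and 11 held with each of the 8 libraries left out in turn. The calls of DCT, CCKBR, HOMER2, SLITRK1, CACNA1E, SEZ6L and ZNF562 ended without any of at least 3 single libraries, with adjusted p up to 0.0903, 0.110, 0.0981, 0.0856, 0.105, 0.205 and 0.0774. Within B16, B27 and B29 the differences of mean log2 CPM were -2.32, -0.73 and -1.06 for SEZ6L and -3.15, -1.67 and -1.11 for CACNA1E. For SLITRK1 they were -2.91, -2.08 and -1.33, and for LOC100288203 -1.94, -0.96 and -1.01. They were 3.73, 2.71 and 1.56 for DCT and 2.49, 1.10 and 1.24 for CCKBR. The labels do not state how many knockout clones were used, so these falls and rises could not be separated from differences of the clone. The number of calls was 14 without wildtype replicate 1, 37 without wildtype replicate 4, 12 without knockout replicate 2 and 13 without knockout replicate 3. Within the B16 libraries alone it was 2032 (620 higher, 1412 lower), and over the B27 and B29 libraries it was 29, of which 14 were among the 22. In the authors' deposited table, 21 of the 22 genes have an adjusted p below 0.05.

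Genes of retina and pigment epithelium were higher in knockout organoids at day 10. Of 14 measured members of this list, 11 had higher values, 1 (DCT) rose over all genes tested and 4 rose when adjusted over the list alone, with a median log2 fold change of 0.67 (camera adjusted p = 2.71e-07; adjusted p = 0.0104 with an estimated correlation). The median was 0.67 within the B16 libraries, 0.32 within B27 and 0.43 within B29. The list was also called over the B27 and B29 libraries alone (camera adjusted p = 0.000704), a fit added after the data were seen.

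Neuronal and neural crest genes were lower in knockout than in wildtype organoids at day 10, and these differences were between the B16 libraries. Of 18 pan-neuronal genes 16 had lower values, 0 were called over all genes tested and 12 fell when adjusted over the list alone, with a median of -1.75 (camera adjusted p = 9.18e-08; adjusted p = 0.471 with an estimated correlation). The RNA-binding protein gene ELAVL4 stood at 22.7 ± 24.5 CPM in wildtype and 0.818 ± 0.436 in knockout, and the neurofilament gene NEFL at 78.1 ± 67.5 and 14.7 ± 1.97. Of 12 neural crest and placode genes, 0 were called over all genes tested and 11 fell when adjusted over the list alone, with a median of -3.94 (camera adjusted p = 6.26e-07; adjusted p = 0.471 with an estimated correlation). The crest transcription factor FOXD3 stood at 26.7 ± 31.7 and 0.489 ± 0.448 CPM, and TFAP2B at 161 ± 191 and 3.61 ± 3.37 CPM. Within B16 the medians were -2.62 for the pan-neuronal and -5.26 for the neural crest list, against -0.24 and -0.11 within B27 and 0.13 and 0.57 within B29.

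**Figure D2:**
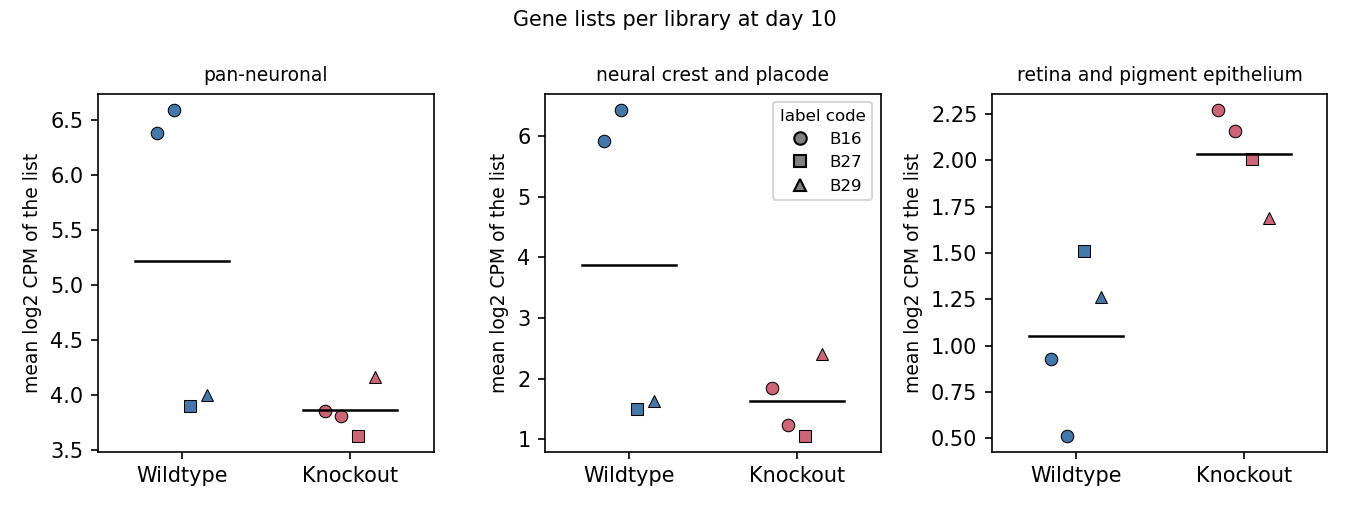
Mean log2 CPM (y axis) of the pan-neuronal, neural crest and placode, and retina and pigment epithelium lists in each day 10 library, by genotype (x axis), with symbols for the label code and lines for group means. Wildtype replicates 1 and 2 lie at 6.38 and 6.59 in the pan-neuronal list against 3.90 and 3.99 in the other wildtype libraries, whereas every knockout library lies above every wildtype library in the retina and pigment epithelium list.

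The other 10 lists called at day 10 lost their call with an estimated correlation. Intermediate progenitor genes were lower in 10 of 12 members (7 lower and 1 higher adjusted over the list alone; median -1.72, camera adjusted p = 0.0185). PPP1R17 stood at 34.9 ± 39.5 and 0.583 ± 0.29 CPM in wildtype and knockout and NHLH1 at 136 ± 156 and 5.61 ± 3.31. SLIT-ROBO and netrin guidance genes, which steer growing axons, were lower in 14 of 18 (4 adjusted over the list alone; median -0.36, camera adjusted p = 0.000167). The ligand SLIT2 stood at 20.1 ± 4.65 and 10.4 ± 2.22 CPM and the netrin receptor DCC at 35.3 ± 22.5 and 10 ± 3.75. Neuronal migration genes had a median of -0.18 (16 of 23 lower, 0 adjusted over the list alone; camera adjusted p = 0.0267). DCX, a microtubule-binding protein of migrating neurons, stood at 61.3 ± 48.9 and 16.4 ± 4.01 CPM and CDK5R1 at 22.7 ± 6.62 and 13.8 ± 2.35. Cajal-Retzius and preplate genes had a median of -0.83 (8 of 11 lower, 5 adjusted over the list alone; camera adjusted p = 0.0395). RELN, the secreted signal that positions cortical neurons, stood at 31.7 ± 37.2 and 1.68 ± 1.23 CPM and EBF3 at 34.3 ± 37 and 2.76 ± 1.67. With an estimated correlation the adjusted p was 0.471 for the first 3 of these lists and 0.518 for the Cajal-Retzius and preplate list. The medians within B16, B27 and B29 were -2.39, 0.03 and 0.26 for intermediate progenitors and -0.61, -0.13 and -0.01 for SLIT-ROBO and netrin guidance. They were -0.40, 0.00 and 0.05 for neuronal migration and -1.96, 0.15 and 0.87 for Cajal-Retzius and preplate. Leaving out wildtype replicate 1 or 2 or knockout replicate 2 ended the call of intermediate progenitors (adjusted p up to 0.0968), neuronal migration (up to 0.2805) and Cajal-Retzius and preplate (up to 0.298), as did knockout replicate 3 for the first and last and knockout replicate 1 for the latter 2.

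Genes of other lineages were also lower. Oligodendrocyte lineage genes had a median of -1.55 (8 of 9 lower, 4 adjusted over the list alone; camera adjusted p = 0.00272). SOX10, a transcription factor shared with the neural crest, stood at 118 ± 136 CPM in wildtype and 7.8 ± 2.95 CPM in knockout. Mesenchyme and fibroblast genes had a median of -1.19 (14 of 15 lower, 1 adjusted over the list alone; camera adjusted p = 0.00108). The collagen gene COL1A2 stood at 394 ± 300.2 and 95.9 ± 17.9 CPM. ER stress and apoptosis genes had a median of -0.24 (13 of 17 lower, 1 adjusted over the list alone; camera adjusted p = 0.00801). PMAIP1, a pro-apoptotic BCL2 family gene, stood at 2.93 ± 1.67 and 0.622 ± 0.301 CPM. Higher in knockout were neuroepithelium genes (median 0.34, 13 of 18 higher, 0 adjusted over the list alone; camera adjusted p = 0.0013). PAX6 stood at 201 ± 18.3 and 259.7 ± 37.8 CPM and SOX3 at 94.2 ± 7.58 and 124 ± 25. Cell cycle genes (median 0.21, 16 of 20 higher, 0 adjusted over the list alone; camera adjusted p = 0.00564) and forebrain identity genes (median 0.10, 9 of 13 higher, 1 adjusted over the list alone; camera adjusted p = 0.0395) were higher as well. The mitotic kinase gene PLK1 stood at 155 ± 30.7 and 204 ± 37.3 CPM and OTX1 at 170.0 ± 20.1 and 250.4 ± 44.1. Within B16, B27 and B29 the medians of log2 CPM differences, in which members without counts give 0, were -1.39, -0.11 and 0.64 for oligodendrocyte lineage. For mesenchyme and fibroblast these medians were -0.69, -0.32 and 0, and for ER stress and apoptosis -0.62, -0.02 and 0.06. They were 0.47, -0.02 and 0.01 for neuroepithelium, 0.43, -0.04 and -0.03 for cell cycle, and 0.40, -0.08 and 0.11 for forebrain identity. The call was lost without knockout replicate 2 or 4 for ER stress and apoptosis (adjusted p up to 0.103), without wildtype replicate 1 or 2 for cell cycle (up to 0.2805), and without wildtype replicate 2 or knockout replicate 1 or 4 for forebrain identity (up to 0.306). With an estimated correlation the adjusted p was 0.518 for cell cycle and 0.471 for the other 5 of these lists. Without the B16 wildtype libraries, 2 lists were called at day 10, retina and pigment epithelium (adjusted p = 1.65e-05) and the semaphorin, plexin and ephrin guidance list, each higher in knockout.

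At day 60 the genotypes were compared in older organoids. FEZ1 and CTSF remained low in knockout organoids, with CTSF at 30.5 ± 1.81 CPM in wildtype and 0.723 ± 0.702 CPM in knockout (log2 fold change -5.36 ± 0.50, adjusted p = 0.00222, n = 2 per genotype, edgeR). GUSBP4 fell with a log2 fold change of -4.70 ± 0.49 (adjusted p = 0.00478). CXCL11, named after its values were seen, had 1 count over the knockout libraries against 182 over the wildtype libraries, a ratio of 174.2 (95% interval 30.9 to 6920; adjusted p = 0.0125). With all 12 libraries in the edgeR fit these 4 were the only genes called, 0 higher and 4 lower, and 995 had an unadjusted p below 0.05. GUSBP4 and CXCL11 lost their call without either knockout library (adjusted p up to 0.264 and 0.325), and the number of calls was 2 without either knockout library and 357 without wildtype replicate 1 (8 higher, 349 lower). DESeq2 called 152 genes (52 higher, 100 lower), and edgeR called 130 with the day 60 libraries alone (99 higher, 31 lower).

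GABAergic and ventral forebrain genes were higher in knockout organoids at day 60. Of 14 measured members 12 had higher values, 0 were called over all genes tested and 9 rose when adjusted over the list alone, with a median log2 fold change of 2.23 (camera adjusted p = 7.55e-22; adjusted p = 0.00363 with an estimated correlation). DLX6 and DLX5, homeobox genes of GABAergic progenitors, stood at 3.12 ± 1.56 and 3.25 ± 1.52 CPM in wildtype against 16.6 ± 0.275 and 21.1 ± 1.5 CPM in knockout. Retina and pigment epithelium genes were higher in 12 of 14 members, with 0 called over all genes tested, 2 adjusted over the list alone and a median of 0.98 (camera adjusted p = 7.89e-10; adjusted p = 0.00363 with an estimated correlation). OTX2 stood at 6.96 ± 0.639 CPM in wildtype and 20.9 ± 0.266 CPM in knockout, and ATOH7, a factor of retinal ganglion cell formation, at 12.5 ± 2.07 and 41 ± 5.17 CPM. The pan-neuronal list had a median of -0.03 at day 60 and was not called (camera adjusted p = 0.91).

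Lists of progenitors and of posterior identity were also higher at day 60, and each lost its call with an estimated correlation. All 20 cell cycle genes had higher values (0 adjusted over the list alone; median 0.48, camera adjusted p = 1.21e-12; adjusted p = 0.103 with an estimated correlation). The thymidylate synthase gene TYMS stood at 18.6 ± 0.629 CPM in wildtype and 29.9 ± 1.02 CPM in knockout, and the values below are in this order. Midbrain and hindbrain identity genes were higher in 15 of 17 (3 adjusted over the list alone; median 1.39, camera adjusted p = 1.27e-12; adjusted p = 0.0513 with an estimated correlation). PAX5 stood at 1.43 ± 0.765 and 5.76 ± 1.61 CPM. Neuroepithelium genes had a median of 0.58 (14 of 18 higher, 1 adjusted over the list alone; camera adjusted p = 2.12e-06; adjusted p = 0.117 with an estimated correlation). PAX6 stood at 234 ± 15.9 and 344 ± 15.2 CPM. Radial glia genes had a median of 0.24 (14 of 15 higher, 0 adjusted over the list alone; camera adjusted p = 0.00201; adjusted p = 0.0697 with an estimated correlation). Outer radial glia genes had a median of 0.23 (10 of 15 higher, 0 adjusted over the list alone; camera adjusted p = 0.00201; adjusted p = 0.0539 with an estimated correlation). HOPX stood at 4.47 ± 0.609 and 13.7 ± 3.58 CPM. The call was lost without wildtype replicate 1 (adjusted p = 0.0781). Hedgehog pathway genes had a median of 0.31 (7 of 11 higher, 1 adjusted over the list alone; camera adjusted p = 0.015; adjusted p = 0.0902 with an estimated correlation). The receptor gene PTCH1 stood at 28.1 ± 3.57 and 52.8 ± 7.26 CPM. The call was lost without wildtype replicate 1 (adjusted p = 0.481) and without knockout replicate 2 (0.397). Cajal-Retzius and preplate genes had a median of 0.73 (9 of 11 higher, 1 adjusted over the list alone; camera adjusted p = 0.0256; adjusted p = 0.427 with an estimated correlation), and were called with 1 of the 4 libraries left out, knockout replicate 1 (adjusted p up to 0.136 without the others).

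Mesenchymal, epithelial and vascular genes were lower in knockout organoids at day 60. Mesenchyme and fibroblast genes were lower in 14 of 15 (8 adjusted over the list alone; median -1.61, camera adjusted p = 4.69e-11; adjusted p = 0.0681 with an estimated correlation). The collagen gene COL3A1 stood at 1213 ± 819 CPM in wildtype and 212 ± 25.7 CPM in knockout, and the proteoglycan gene DCN at 122 ± 97.2 and 19.4 ± 6.97. Wildtype replicate 2 had the higher values (COL3A1 1792 against 634.0 CPM, DCN 190.2 against 52.8 CPM). Without it the log2 fold changes were -1.58 for COL3A1 and -1.45 for DCN, against -2.51 and -2.65, and the median of the mesenchyme and fibroblast list was -1.02 (camera adjusted p = 6.34e-08). Non-neural epithelium genes were lower in 10 of 12 (8 adjusted over the list alone; median -2.46, camera adjusted p = 1.26e-08; adjusted p = 0.103 with an estimated correlation). The keratin gene KRT8 stood at 57.8 ± 76 and 5.38 ± 0.651 CPM, with 4.06 CPM in wildtype replicate 1 and 111.5 CPM in wildtype replicate 2. Without wildtype replicate 2 its log2 fold change was 0.41, against -3.42 with all libraries. The mean log2 CPM of this list was 3.28 in wildtype replicate 2 against 0.70 in wildtype replicate 1 and 0.37 and 0.88 in knockout, and without wildtype replicate 2 the call was lost (adjusted p = 0.572). Genes of endothelium, blood and microglia were lower in all 8 members (2 adjusted over the list alone; median -1.10, camera adjusted p = 0.000115; adjusted p = 0.103 with an estimated correlation). The endothelial cadherin gene CDH5 stood at 10.9 ± 14.6 and 0.133 ± 0.0278 CPM, with 0.573 CPM in wildtype replicate 1 and 21.2 CPM in wildtype replicate 2. The call was lost without wildtype replicate 2 (adjusted p = 0.586). Choroid plexus genes had a median of -0.78 (9 of 12 lower, 2 adjusted over the list alone; camera adjusted p = 0.00164; adjusted p = 0.117 with an estimated correlation) and lost the call without the same library (adjusted p = 0.672). Synaptic genes had a median of -0.20 (15 of 18 lower, 1 adjusted over the list alone; camera adjusted p = 0.026; adjusted p = 0.381 with an estimated correlation). The synapsin gene SYN2 stood at 15.9 ± 1.41 and 9.19 ± 0.926 CPM. The call was lost without wildtype replicate 1 (adjusted p = 0.845) and without knockout replicate 2 (0.177).

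**Figure D3:**
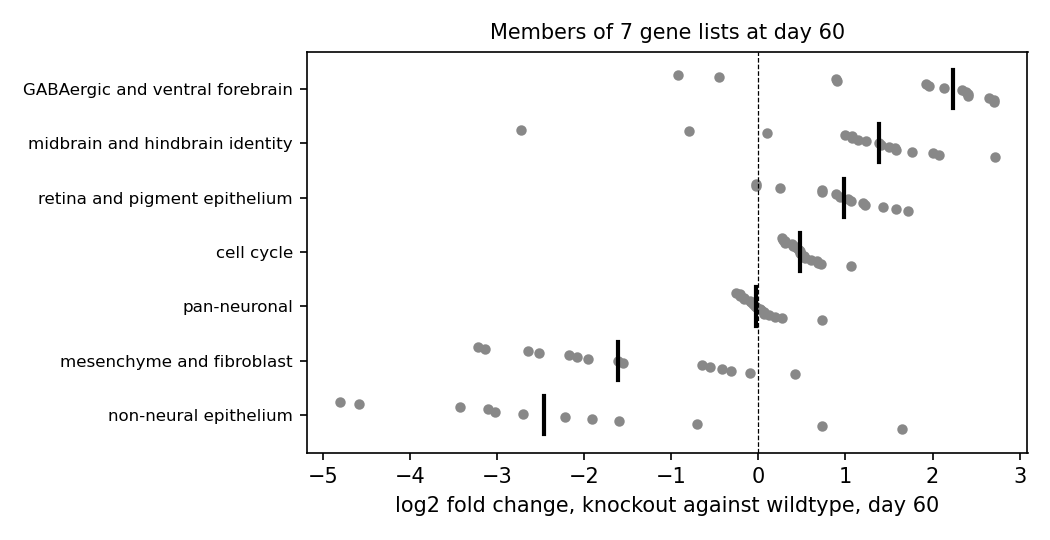
Log2 fold changes of knockout against wildtype at day 60 (x axis) for the measured members of 7 gene lists (y axis), with 1 point per gene and a bar at the median of the list. The medians run from 2.23 in the GABAergic and ventral forebrain list to -2.46 in the non-neural epithelium list, with -0.03 in the pan-neuronal list.

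The effects at the 2 days were set side by side to see which genes responded at each. All 4 genes lower at day 60 (FEZ1, CTSF, GUSBP4 and CXCL11) were among the 15 lower at day 10, where 0.00338 would be shared by independent lists. Of the day 10 calls, 14 of the 15 lower and 6 of the 7 higher genes had the same sign at day 60. Some of these had day 60 log2 fold changes near 0, such as UBBP4 (0.03), PIWIL2 (0.05), LOC100288203 (-0.06) and SEZ6L (-0.11). ZNF280D, PEG3 and CCDC152 had day 60 log2 fold changes of -2.29 ± 0.38, -4.44 ± 0.86 and 1.82 ± 0.35, which did not pass the test (adjusted p = 0.149, 0.241 and 0.241). Across all 17757 genes, which are not independent replicates, the log2 fold changes of the days had a Pearson r of 0.0117 and a Spearman rho of 0.0135. No library was shared by the comparisons. In the test of the difference between days, edgeR called 0 genes, with 1269 at an unadjusted p below 0.05, and DESeq2 called 80. FEZ1 had an interaction of -1.07 ± 0.19 (adjusted p = 0.467). Without wildtype day 60 replicate 1, edgeR called 193 genes.

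Day 60 was compared with day 10 in wildtype organoids to describe their maturation. The cortical neuron transcription factor NEUROD6 rose from 1 count over the day 10 libraries to 312 ± 90.6 CPM at day 60, a ratio of 24436 (95% interval 4385 to 965235), and NEUROD2 rose with a log2 fold change of 11.77 ± 0.45. The stem cell RNA-binding protein gene LIN28A fell from 1569 ± 358 to 0.459 ± 0.207 CPM. The posterior HOX genes HOXB5, HOXB8 and HOXB6 were at least 1582-fold, 1372-fold and 933.5-fold higher at day 60, and the collagen gene COL3A1 rose by 11.99 ± 0.62. CD8B2 was at least 289.4-fold lower at day 60, VENTX at least 83.4-fold and FOXI2 at least 81.6-fold, and the homeobox gene BARHL1 fell with a log2 fold change of -9.16 ± 2.15. At day 10 FOXI2 stood at 9.18 and 14.1 CPM in wildtype replicates 1 and 2 and at 0.514 and 0.342 CPM in replicates 3 and 4, and BARHL1 at 97.7 and 139.2 CPM against 6.99 and 6.56 CPM. Without wildtype replicates 1 and 2 of day 10, a fit added after the data were seen, BARHL1 had a log2 fold change of -5.98. FOXI2 lost its call without either wildtype day 60 library (adjusted p up to 0.0783). In total 9837 genes were called, 5195 higher and 4642 lower at day 60.

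Of the 32 lists tested, 14 were called between days in wildtype, 8 higher and 6 lower at day 60. For this comparison, the members said to rise or fall are those called in that direction over all genes tested. Uncalled members are not in these counts, whatever their sign. Pluripotent stem cell genes fell in 10 of 11 members (also 10 adjusted over the list alone; median -3.85, camera adjusted p = 3.58e-11; adjusted p = 0.0098 with an estimated correlation), among them DPPA4 (-5.81 ± 0.30) and L1TD1 (-5.03 ± 0.24). Cortical excitatory neuron genes rose in 11 of 16 (12 adjusted over the list alone; median 2.78, camera adjusted p = 4.84e-11; adjusted p = 0.0433 with an estimated correlation), among them BCL11B (4.86 ± 0.26). The other 12 lists lost their call with an estimated correlation. Pan-neuronal genes rose in 11 of 18 (12 adjusted over the list alone; median 2.35, camera adjusted p = 8.51e-06; adjusted p = 0.386 with an estimated correlation), among them NSG1 (3.50 ± 0.13) and SYT1 (2.76 ± 0.17). The mean log2 CPM of this list was 6.38 and 6.59 in wildtype day 10 replicates 1 and 2, and 3.90 and 3.99 in replicates 3 and 4. At day 60 it was 8.41 and 8.08, so the size of the rise depends on the day 10 libraries. Synaptic genes rose in 15 of 18 (16 adjusted over the list alone; median 2.23, camera adjusted p = 1.31e-08; adjusted p = 0.105 with an estimated correlation), among them the NMDA receptor gene GRIN2B (4.18 ± 0.29). Genes of kinesin transport and FEZ1 partners rose in 15 of 22 (15 adjusted over the list alone; median 1.33, camera adjusted p = 1.23e-05; adjusted p = 0.122 with an estimated correlation), among them KIF5A (4.32 ± 0.34) and KIF3C (3.28 ± 0.22). Mesenchyme and fibroblast genes rose in 14 of 15 (14 adjusted over the list alone; median 3.17, camera adjusted p = 2.75e-05; adjusted p = 0.24 with an estimated correlation).

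Of 20 cell cycle genes, 19 were called as lower at day 60 than at day 10 in wildtype (20 adjusted over the list alone; median -1.57, camera adjusted p = 8.3e-09; adjusted p = 0.24 with an estimated correlation), among them TYMS (-2.20 ± 0.21) and BIRC5 (-2.12 ± 0.22). The counts below are also of called members. Hypoxia and glycolysis genes fell in 14 of 19 (14 adjusted over the list alone; median -2.13, camera adjusted p = 1.94e-08; adjusted p = 0.122 with an estimated correlation), among them the lactate dehydrogenase gene LDHA (-3.60 ± 0.14) and PGK1 (-2.58 ± 0.13). WNT pathway genes fell in 13 of 22 (13 adjusted over the list alone; median -1.93, camera adjusted p = 8.92e-05; adjusted p = 0.24 with an estimated correlation), among them SP5 (-7.77 ± 0.45) and LEF1 (-2.73 ± 0.22). Midbrain and hindbrain identity genes (median 1.14, 8 of 17 rose, 8 adjusted over the list alone; camera adjusted p = 0.00719), GABAergic and ventral forebrain genes (median 2.16, 8 of 14 rose, 8 adjusted over the list alone; camera adjusted p = 0.0239) and intermediate progenitor genes (median 0.64, 5 of 12 rose, 5 adjusted over the list alone; camera adjusted p = 0.0332) were higher, with adjusted p of 0.337, 0.386 and 0.42 with an estimated correlation. Neuroepithelium genes (median -0.62, 7 of 18 fell, 7 adjusted over the list alone; camera adjusted p = 0.00694) and neural crest and placode genes (median -4.88, 8 of 12 fell, 8 adjusted over the list alone; camera adjusted p = 0.039) were lower, with adjusted p of 0.386 and 0.604 with an estimated correlation. The mean log2 CPM of the neural crest and placode list was 5.92 and 6.43 in wildtype day 10 replicates 1 and 2, 1.504 and 1.636 in replicates 3 and 4, and 0.96 and 1.14 at day 60. Without replicates 1 and 2 of day 10, a fit added after the data were seen, its median was -0.52 (adjusted p = 0.252). The intermediate progenitor list had a mean log2 CPM of 4.87 and 4.97 in wildtype day 10 replicates 1 and 2. It stood at 2.02 and 2.27 in replicates 3 and 4, and at 5.82 and 5.59 at day 60. The size of its rise thus depends on the day 10 libraries. The neural crest and placode call was lost without wildtype day 10 replicate 1 or 2 or either day 60 wildtype library (adjusted p up to 0.0821), and the intermediate progenitor call without wildtype day 10 replicate 3 (0.0558).

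Knockout organoids were compared between the same days to see whether maturation differed. In them 10227 genes were called, 5444 higher and 4783 lower at day 60. Of the genes called in either genotype, 8400 changed in the same direction in both, 3 in opposite directions, 1434 were called in wildtype alone and 1824 in knockout alone, with a Pearson r of 0.866 across genes. A call in 1 genotype alone does not test a difference in maturation. That test is the interaction, in which edgeR called 0 genes and DESeq2 called more, as given above. The neuronal gene NSG1 stood at 19.1 ± 1.44 CPM at day 10 and 171 ± 10.4 CPM at day 60 in knockout, against 16.1 ± 1.16 and 181 ± 22.3 CPM in wildtype, and LDHA at 1269.5 ± 89.6 and 137 ± 7.57 CPM in knockout, against 1338 ± 57.2 and 110.5 ± 8.02 CPM in wildtype. These comparisons share no library.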

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

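The tests weighed in this part, the other splits of the samples and the comparison of lists between days were chosen after the results were seen.

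Among the 8 day 10 libraries, 116 sets of 4 values were searched for a library far from the other 3, and 4 were found where chance gives about 5.80. The search looks for 1 library apart from the rest. It cannot find a pair, such as wildtype replicates 1 and 2, at 6.38 and 6.59 in mean log2 CPM of the pan-neuronal list against 3.90 and 3.99 in replicates 3 and 4. The low number found is thus no sign that the libraries are alike. FAS stood at 1.23 CPM in wildtype replicate 3 against 1.07 to 1.09 in the other wildtype libraries. ZNF562 stood at 78.1 CPM in wildtype replicate 1 against 67.6 to 69.0. POSTN stood at 0.0643 CPM in knockout replicate 4 and had 0 counts in the other knockout libraries. The 50 most abundant genes took 16.99% of the counts of knockout replicate 1 against 13.1% to 13.6% in the other knockout libraries.

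The knockout effect differed between day 10 and day 60 for 13 lists by camera, and for 0 with an estimated correlation and 0 by fry. Relative to day 10, the effect at day 60 was higher for the GABAergic and ventral forebrain (adjusted p = 1.28e-12), neural crest and placode (2.74e-06), midbrain and hindbrain identity (1.38e-05), pan-neuronal (4.10e-05), Cajal-Retzius and preplate (0.00103), cell cycle (0.00301), SLIT-ROBO and netrin guidance (0.00676), neuronal migration (0.0110), radial glia (0.0250), intermediate progenitors (0.0278) and oligodendrocyte lineage (0.0278) lists. It was lower for non-neural epithelium (7.26e-07) and for endothelium, blood and microglia (0.00143). Within B16 the day 10 medians were -5.26 for neural crest and placode, -2.62 for pan-neuronal and -2.39 for intermediate progenitor genes. They were -0.11, -0.24 and 0.03 within B27 and 0.57, 0.13 and 0.26 within B29. The GABAergic and ventral forebrain list had smaller medians within codes (-0.41 within B16, 0.05 within B29). Its mean log2 CPM still set wildtype day 10 replicates 1 and 2 apart. It was 0.89 and 0.96 in them, against -1.19 and -0.86 in wildtype replicates 3 and 4. In the day 10 knockout libraries it lay between -1.16 and -0.59. The difference between days for this list may thus also rest in part on wildtype replicates 1 and 2. This comparison of lists was not repeated without wildtype day 10 replicates 1 and 2.

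Neuronal and neural crest genes were lower in knockout at day 10 because wildtype replicates 1 and 2, both coded B16, had high values of these genes. A difference between the label codes shared by both genotypes is argued against, since the pan-neuronal median of the B16 knockout libraries differed from that of the other knockout libraries by -0.165, against 2.37 in wildtype. A knockout effect of this size in every code is argued against by a median log2 fold change of -0.0395 over the B27 and B29 libraries. Mislabelled genotypes are argued against by FEZ1, which stood at 40.5 CPM or more in these 2 libraries and at 22.7 CPM or less in knockout. A knockout effect that appears only among the libraries coded B16, or a feature of these 2 wildtype libraries unrelated to FEZ1, may account for the pattern, and neither could be tested.

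Chance could not be excluded for the number of genes called at day 10, since 2 of the 35 splits of the 8 libraries into 4 and 4 gave at least the real 22. The other was the split of the B16 libraries against the rest, with 2007 genes, the highest of the other splits, which points to a structure of the samples. No further split gave more than 3 genes. Within the B16 libraries the genotypes differed in 2032 genes, and with the code as a covariate in 43. Chance could not be excluded for the number of lists called at day 10 either, where 10 of the 35 splits gave at least the real 13 and the highest other gave 18. All 10 keep wildtype replicates 1 and 2 together, and no split that parts them gave more than 4 lists, which points to these 2 libraries.

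GABAergic and ventral forebrain genes were higher in knockout at day 60. Other cell types in wildtype replicate 2, which had more epithelial and endothelial transcripts, are argued against, since the median was 1.91 without that library and the list was still called. A lower share of neurons in wildtype is argued against by the pan-neuronal median of -0.0310. Every knockout library lay above every wildtype library, with a gap of 1.38 in the mean log2 CPM of the list, but 2 libraries per genotype give only 3 splits. All day 60 libraries carry B16, so the difference could not be compared between codes. An effect of FEZ1, a difference of the knockout clone and variation between cultures in regional identity cannot be told apart here. Any of these may account for the difference.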

How the results depend on the processing

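Alternatives fixed beforehand and those added after the data were seen (a DESeq2 fit with day 60 as 1 group, B27 and B29 libraries, and the fit without the B16 wildtype libraries of day 10) are given together. Unless said otherwise, the cause of a change was not tested.

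At day 10, 22 genes were called with the other size factors, 27 without a filter, 19 with a stricter one, 21 without robust estimation and 16 with the day 10 libraries alone. The count was 43 with the code as a covariate (19 of the 22 shared), 2032 in the B16 libraries (22 shared), 499 with DESeq2, 542 with DESeq2 and day 60 as 1 group, 29 in the B27 and B29 libraries and 13 without the B16 wildtype libraries. At day 60, 4 genes became 9 in the B16 libraries, 152 with DESeq2 and 130 with the day 60 libraries alone (3 shared), where CTSF lost its call (adjusted p = 0.0684, the highest over its 13 alternatives). FEZ1 at day 60 was called in all 13 (adjusted p up to 0.0391). FEZ1 at day 10 was called in 18 of 20, with -1.09 and an adjusted p of 0.179, the highest of the 20, with DESeq2 and day 60 as 1 group, since the varied day 60 libraries then raise its spread. The interaction, 0 genes with edgeR (1269 at an unadjusted p below 0.05), gave 1 with the covariate, 908 in the B16 libraries, 80 with DESeq2 and 50 with the B27 and B29 libraries. The 9837 and 10227 genes called between days stayed within 1.5 times their number in every alternative. Over the genes called at either day alone, the agreement of the days was 0.793. These genes were chosen for their effects in the same libraries, which can raise this value.

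The number of lists called at day 10 fell from 13 to 1 with an estimated correlation, 1 with fry, 6 in the B27 and B29 libraries and 2 without the B16 wildtype libraries. At day 60 it fell from 14 to 2 with an estimated correlation and 3 with fry. Between days in wildtype, 14 became 2 with an estimated correlation and 24 with fry.

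Uncalled genes changed sign at day 10 in the B27 and B29 libraries: NHLH1 (1.01), EBF3 (0.70), RELN (2.07), TFAP2C (1.07), SOX10 (0.50), POSTN (0.17) and TFAP2B (0.80). Without the B16 wildtype libraries NHLH1 (0.78), EBF3 (0.12), RELN (1.45), TFAP2C (0.91), SOX10 (0.55) and TFAP2B (0.28) did so. The dropped wildtype libraries had high values of these genes, so the signs over all libraries depend on them. Why these values were high was not tested. For POSTN the changed sign rests on few counts, with 0.0514 CPM in wildtype replicate 3, 0.0643 CPM in knockout replicate 4 and 0 in wildtype replicate 4 and knockout replicate 3.

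With 1 library left out, the day 10 count ran from 12 (without knockout replicate 2) to 37 (without wildtype replicate 4), with 14 without wildtype replicate 1 and 13 without knockout replicate 3. Calls ended without these wildtype (W) or knockout (K) replicates, with the highest adjusted p: DCT W1, W2, W3, K1, K2 (0.0903), CCKBR W1, W2, W3, K2 (0.110), HOMER2 W1, W2, W3, K2, K3 (0.0981), SLITRK1 W1 and all K (0.0856), CACNA1E W1, K1, K2, K3 (0.105), SEZ6L W1, W2 and all K (0.205), ZNF562 W1, K2, K3 (0.0774), ART3 K1, K3 (0.0799), TSPYL5 K1, K2, K3 (0.0769), LINC00680-GUSBP4 W1 to W3 and K1 to K3 (0.0720) and LOC100288203 all but W4 (0.181). The day 60 count ran from 2 (without either knockout library) to 357 (without wildtype replicate 1), and the lone library left is assumed to vary like the other groups. The interaction ran from 0 to 193 (without wildtype day 60 replicate 1), the day 10 lists from 8 (without wildtype replicate 2) to 16. FEZ2 at day 60 ran from -0.0877 to 0.0785 without wildtype replicate 1 (also above 0 without knockout replicate 2), and KRT8 from -4.36 without wildtype replicate 1 to 0.41 without wildtype replicate 2, a library with high epithelial values.

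The labels do not say that replicate numbers pair the genotypes. At day 10 libraries of the same number had correlations of their deviations from 0.30 to -0.10, and numbers 1 and 3 but not 2 and 4 correlated best with their own, while 2 libraries per genotype at day 60 (0.12) cannot show it. With the number as a block, which uses up degrees of freedom, 8 genes were called at day 10, and FEZ1 (-1.11) had an adjusted p of 0.0516 (up to 0.179 over its alternatives).

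Depth limits genes with few counts, such as CXCL11, whose day 60 ratio of 174.2 has an interval of 30.9 to 6920.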

Other observations

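The comparison within the B27 and B29 libraries, the genes named from it and the search along chromosomes were chosen after the data were seen.

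In the B27 and B29 libraries of day 10, with 2 libraries per genotype, the growth factor genes FGF17 and FGF8 were lower in knockout, with log2 fold changes of -2.17 ± 0.20 (SE; adjusted p = 0.00289) and -0.99 ± 0.11 (0.00728). In the B16 libraries the difference ran the other way, with FGF17 at 4.37 and 0.730 CPM in wildtype against 10.3 and 8.03 in knockout, and FGF8 at 20.3 and 8.44 against 60.6 and 38.1. Over all day 10 libraries the log2 fold changes were -0.94 and 0.06, and neither gene was called. Also lower in it, but not called over all day 10 libraries, were DMTN (-1.21), EMC10 (-1.09), GNG4 (-0.93), ANKRD13B (-0.78) and TNFAIP2 (-0.78). Higher in it, but not called over all day 10 libraries, were LY6H (2.34), TNFRSF19 (0.94), ATP1B2 (0.67), FGFR2 (0.66), MIAT (0.62), NLGN2 (0.56) and TRAPPC1 (0.56). Of these, DMTN and TNFAIP2 were higher on average and TNFRSF19, FGFR2 and MIAT lower on average in knockout in the B16 libraries, with TNFRSF19 at 94.9 and 120.2 CPM in wildtype against 36.3 and 55.4 in knockout.

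A run of 37 neighbouring genes on chromosome 17, from 7281667 to 8163546 (GRCh38), was higher in knockout at day 10, with EIF5A and POLR2A among them. It was chosen as the run with the highest sum of day 10 log2 fold changes after 0.3 was taken from each. All 37 had higher values (median log2 fold change 0.64, SD 0.27), 32 had an unadjusted p below 0.05 and 0 were called by edgeR over all day 10 libraries (3 in the B27 and B29 libraries, NLGN2, TRAPPC1 and ATP1B2), while the highest of 11737 other windows of 37 genes had a median of 0.298. The flanking 37 genes on each side had medians of 0.08 and -0.06. These day 10 values follow in part from the choice of the run, and the windows overlap each other. The same limit holds for the other day 10 comparisons with windows below. The segment has a median GC content of 57.2% against 49.0% over the genes scanned, but GC bias is argued against, since the median was 0.564 after the trend was removed and the highest other window then had 0.160. The unusual composition of knockout replicate 1 is argued against by a median of 0.465 without it, against 0.176 in the highest other window. In the day 60 libraries, which had no part in choosing the segment, its median was 0.263 (SD 0.33, 30 of 37 genes higher), above the 0.170 of the highest other window, and each knockout library lay above each wildtype library. At day 60, 3 of its genes had an unadjusted p below 0.05 by edgeR. A copy-number difference between the lines may account for this, as a gain in knockout or a loss in wildtype. A gain from 2 to 3 copies would give 0.585, and the day 60 median of 0.263 lies below this. DNA was not measured.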
